A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

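The series holds 8 RNA-seq libraries of Saccharomyces cerevisiae. There are 2 for each combination of genotype (labelled wild type or mub1 deletion) and medium (0 or 20 µg/ml Calcofluor white for 5 hours). The labels name strain BMA41 for both genotypes. Per the labels' protocols, RNA was extracted with hot phenol, treated with DNase, enriched for polyadenylated transcripts and made into stranded libraries that were sequenced in pairs. Reads were checked with FastQC 0.12.1, aligned to build R64 with HISAT2 2.2.1 and counted per gene with featureCounts 2.0.3, per the submitters' processing notes. The deposited table holds whole-number counts per gene and library, which the authors did not scale. It has 6534 gene identifiers, and no row is a total or an unassigned category. The notes name neither the strand setting of the counting nor how reads over overlapping genes or with several alignments were treated. Values of genes with a near-identical copy (such as RPS28A and RPS28B, PHO11 and PHO12, IMD1 and IMD2, SOR1 and SOR2, histones, hexose transporters and other ribosomal protein pairs) and of overlapping genes are therefore uncertain.

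Systematic names were matched to the RefSeq annotation of build R64, from which symbols and coordinates were taken. Of the identifiers, 5864 matched and 670 did not. The unmatched ones took 0.16% to 0.229% of the counts of a library and stayed in the tests under their systematic names. Total counts ran from 24147195 to 31677985, so counting error is small for most genes. The floor of 3 counts, the limit that a count of 0 allows, is 0.0947 to 0.124 CPM. Intervals and floors cover counting error only, since PCR copies are not independent molecules. For genes with 1 to 3 counts in a group the ratio is given with an exact 95% binomial interval (Clopper-Pearson), and for 0 counts as a lower bound against 3 counts over the group.

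Counts were analysed in R 4.3.3 with edgeR 4.0.16. filterByExpr kept 5954 genes, which hold 99.997% of the counts, and left out 580 identifiers. TMM factors ran from 0.9793 to 1.024. All 8 libraries entered 1 fit with a mean per group and no further terms, which leaves 4 residual degrees of freedom, and robust quasi-likelihood F tests (glmQLFit and glmQLFTest) were run for mub1 against wild type in each medium, for Calcofluor white in each genotype and for the interaction. P-values were adjusted by Benjamini-Hochberg over the tested genes of each comparison, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F.

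Before the data were examined, 49 gene lists were fixed from textbook knowledge (910 members written by name, 7 of which matched no identifier or no unique one, and 4 lists by name patterns). The pattern for cytosolic ribosomal proteins also took in RPP1, a subunit of ribonuclease P, and that for mitochondrial ones MRP8, and both were left in. Each list was tested with camera (limma 3.58.1), two-sided, with the preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 49 lists. The same test was run with a correlation estimated for each list. No call in any of the 5 comparisons held in it: the lowest adjusted p were 0.613, 0.453, 0.171, 0.592 and 0.404, and 2, 3, 5, 2 and 5 lists had an unadjusted p under 0.05. Counts of members that rose or fell use the adjusted p over all tested genes, and beside them stand those adjusted over the list alone.

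Genes were named by a rule fixed before the data were examined. For each comparison of 2 groups it takes the 8 largest increases and 8 largest decreases among genes past the threshold with a mean of at least 10 CPM over all libraries and no overlap between the groups, and for the interaction the 6 largest in each direction without the overlap condition. MUB1 and its neighbours on the chromosome, UBR2, RAD6, RPN4, SLT2, RLM1, GSC2, CHS3, CRH1, PIR3, PST1, PDR5, YAP1, CUP9, HSF1, PDR1 and PDR3 were always to be reported, and up to 4 members per list with the smallest p serve as examples. The marker genes ADE2, HIS3, LEU2, TRP1 and URA3 were also chosen beforehand, as a check of the labels, and stand outside that rule. MET17 came in by the size rule, and genes named outside the rule are said to be so.

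The steps were tested on simulated data drawn from negative binomial distributions with each gene's mean over all libraries, its estimated dispersion and the real library sizes, with 50 genes changed at each of 4 sizes. At a log2 change of 0.5 the tests recovered 72% (mub1 against wild type without CFW), 70% (with CFW), 74% (CFW in the wild type), 76% (CFW in mub1) and 42% (interaction) of the changed genes, at 1 they recovered 94%, 98%, 98%, 98% and 94%, and 10 to 19 unchanged genes were called. In the simulation of CFW in the wild type camera found a planted list with either correlation (adjusted p = 2.68e-52 and 0.00314). None of 48 unchanged lists was called with either. Genes were drawn independently there, whereas the estimated correlation was 0.829 for the list of Rlm1 targets in that comparison of the real data. The run therefore cannot show how often the preset correlation calls unchanged lists whose members vary together.

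Alternatives fixed beforehand for counts of changed genes were other scalings (RLE, upper-quartile, library totals), no low-count filter or a minimum of 10 CPM, limma-voom, DESeq2 1.42.0, only the groups compared, the replicate number as a block, a fold threshold of 2 and leaving out each library in turn. Named genes had all of these but the fold threshold. Gene lists and correlations had RLE and library totals, the 2 filters, the block and each library left out, and lists also an estimated correlation. The correlation of 2 comparisons was computed across genes and set against data simulated with no effect. The random gene lists of the closing were matched on mean expression in 10 bins, with 10000 draws, and members already named as leading genes or list examples of a genotype comparison were left out of that test. Figures were drawn from these values.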

Results

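Gene expression was measured by sequencing polyadenylated RNA from the budding yeast Saccharomyces cerevisiae. Exponentially growing cells of 2 genotypes were used, labelled wild type and mub1 deletion, and the labels name strain BMA41 for both. The cells were kept for 5 hours in chemically defined medium with 0 or 20 µg/ml Calcofluor white (CFW). This dye binds chitin and disturbs the assembly of the cell wall. MUB1 encodes a protein that works with the ubiquitin ligase Ubr2, whose best known target is Rpn4, the transcription factor of the proteasome genes. The 4 groups of genotype and medium held 2 libraries each, and the 8 libraries held between 24147195 and 31677985 counts over 6534 annotated genes. A count of 0 in 1 library allows a level of up to 0.0947 to 0.124 CPM, the count scaled to the library total, as far as counting error goes. Of the variance of log2 CPM over 5954 tested genes, 59.2% lay on a component that parted the genotypes and 18% on a component that parted the media. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these libraries.

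MUB1 (YMR100W, chromosome XIII, 466300 to 468162, plus strand, a single coding exon in build R64) had 1068, 1066, 1042 and 1226 counts in the libraries labelled wild type and 1, 0, 0 and 1 in those labelled mub1. Its level was thus 2145 times higher in the libraries labelled wild type without CFW (95% counting interval 384.5 to 84760) and 2622 times higher with CFW (470.1 to 103600). Its chromosomal neighbours YMR099C (-0.15 ± 0.07 on the log2 scale, mub1 against wild type without CFW, ± SE) and SRT1 (0.57 ± 0.28) did not pass the test. Other genes also parted the genotypes completely. LEU2 (leucine synthesis, YCL018W) had 1, 1, 2 and 0 counts in the libraries labelled wild type against 4933, 6421, 5053 and 7122 in those labelled mub1. URA3 (uracil synthesis, YEL021W) had 1, 0, 0 and 0 against 5950, 6222, 6122 and 6648. MET17 (sulfur assimilation, YLR303W, formerly MET15) had 1, 0, 0 and 0 against 2621, 2748, 4245 and 4538. TRP1 (tryptophan synthesis, YDR007W) went the other way, with 989, 935, 909 and 976 counts in the libraries labelled wild type and 0 in all 4 labelled mub1, so it was at least 644.6-fold lower without CFW and at least 726.4-fold lower with CFW, against a floor of 3 counts over the group. Other marker genes chosen beforehand, ADE2 (-1.66 ± 0.07) and HIS3 (-1.62 ± 0.09), were present in both genotypes but lower in mub1 without CFW. These genes are common selection markers of laboratory strains, and the genotype comparisons that follow are between libraries that differ in MUB1, in the presence of 4 marker genes and in the level of these others.

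**Figure D1:**
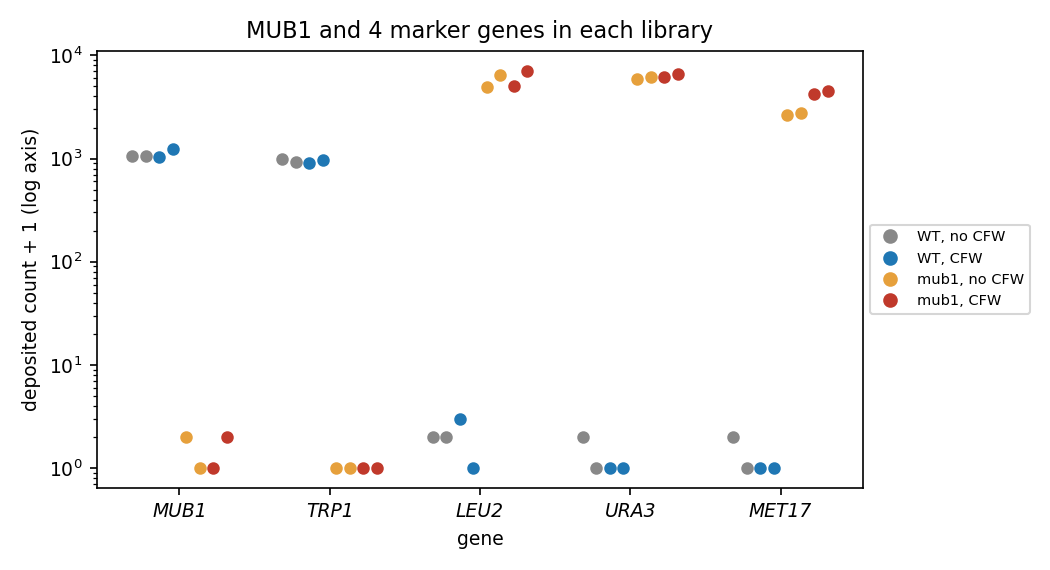
Deposited counts plus 1, on a log axis, of MUB1 and 4 marker genes in each of the 8 libraries, 1 point per library, coloured by group. TRP1 and MUB1 were near 1000 counts in the libraries labelled wild type and at 0 or 1 in those labelled mub1, and LEU2, URA3 and MET17 showed the reverse, with 2621 to 7122 counts in the libraries labelled mub1.

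The comparison of the genotypes without CFW asks what differs before any cell wall stress. The largest increases in the mub1 libraries, after URA3, LEU2 and MET17, were in GAP1, the general amino acid permease (5.96 ± 0.14, a 62.05-fold rise), ADH4, an alcohol dehydrogenase (5.62 ± 1.06), YOR387C (5.35 ± 0.20), PUT4, the proline permease (4.76 ± 0.29), and MEP2, the ammonium permease (4.69 ± 0.13), all log2 ± SE with n = 2 libraries per group. After TRP1 and MUB1, the largest decreases were in SPL2, a regulator of phosphate uptake (-5.24 ± 0.32), CHA1, the serine and threonine deaminase (-4.84 ± 0.12), and QDR2, a drug and ion exporter (-3.60 ± 0.09). LEU1, of leucine synthesis (-3.29 ± 0.14), OAC1, a mitochondrial oxaloacetate carrier (-2.92 ± 0.18), and PHO5, the secreted acid phosphatase (-2.79 ± 0.18), fell as well. The naming rule required that both libraries of one group lay beyond both of the other in each of these genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2554 of 5954 genes changed, 1316 higher and 1238 lower in mub1, and 278 of them changed at least 2-fold (196 higher, 82 lower). With upper-quartile scaling the split was 1209 higher and 1428 lower. Both the MUB1 deletion and the 4 marker genes part the same libraries, and the count was 1440 without wild type, no CFW, replicate 2, 1697 without replicate 1 of that group and 1529 without mub1, no CFW, replicate 1. Of the 16 genes named by size, ADH4 alone lost its call, without either wild-type library or without mub1, no CFW, replicate 1 (adjusted p up to 0.0706, from 1.334e-15 over all alternatives).

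Several mitochondrial lists were called higher without CFW in the libraries labelled mub1, which also differed in LEU2, URA3, MET17 and TRP1. Of the 67 tested mitochondrial ribosomal proteins, 62 rose, 0 fell and 5 did not pass (65 rose and 0 fell adjusted over the list alone). For mitochondrial ribosomal proteins the median log2 was 0.57 (camera adjusted p = 4.13e-18, adjusted p = 0.613 with an estimated correlation). MRPL32 (0.94 ± 0.08), MRPL27 (0.87 ± 0.08) and MRPL11 (0.80 ± 0.07) were among them. Among 33 genes of the respiratory chain and ATP synthase, 30 rose, 0 fell and 3 did not pass (30 rose and 0 fell adjusted over the list alone). Over the respiratory chain the median log2 was 0.72 (camera adjusted p = 2.04e-13, adjusted p = 0.89 with an estimated correlation). CYC1, which encodes cytochrome c, rose by 2.91 ± 0.10, RIP1 by 1.29 ± 0.13 and COX5A by 1.18 ± 0.12. Citric acid cycle genes, of which 20 were tested, moved the same way: 12 rose, 2 fell and 6 did not pass (14 rose and 3 fell adjusted over the list alone). The citric acid cycle had a median log2 of 0.43 (camera adjusted p = 0.01, adjusted p = 0.89 with an estimated correlation). ACO1 rose by 1.03 ± 0.11 and SDH2 by 1.02 ± 0.13. In the ergosterol pathway (25 genes), 15 rose, 4 fell and 6 did not pass (15 rose and 5 fell adjusted over the list alone). For ergosterol synthesis the median log2 was 0.31 (camera adjusted p = 0.0307, adjusted p = 0.89 with an estimated correlation), led by ERG28 (1.25 ± 0.07), HMG1 (0.96 ± 0.09) and ERG11 (0.90 ± 0.09). This list lost its call without either wild-type library lacking CFW or without mub1, no CFW, replicate 2 (adjusted p 0.0511 to 0.0816).

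Other groups without CFW, in the same libraries with their marker differences, differed as well. The phosphate regulon controlled by Pho4 (17 genes) was lower: 1 rose, 9 fell and 7 did not pass (1 rose and 10 fell adjusted over the list alone). Over the phosphate regulon the median log2 was -0.85 (camera adjusted p = 4.74e-07, adjusted p = 0.613 with an estimated correlation), with PHO84, the phosphate transporter, at -1.85 ± 0.09 and VTC1 at -1.02 ± 0.08. All 7 genes of the a-cell marker list fell: 0 rose, 7 fell and 0 did not pass (0 rose and 7 fell adjusted over the list alone). A-cell markers had a median log2 of -0.98 (camera adjusted p = 5.19e-06, adjusted p = 0.89 with an estimated correlation). MFA1, a precursor of the a-factor pheromone, was at -2.34 ± 0.19, AGA2 at -1.83 ± 0.18 and BAR1 at -1.20 ± 0.15. The mating response list (18 genes) gave these calls: 1 rose, 10 fell and 7 did not pass (1 rose and 10 fell adjusted over the list alone). For the mating response the median log2 was -0.47 (camera adjusted p = 0.00319, adjusted p = 0.89 with an estimated correlation), with FUS1 at -0.90 ± 0.12 and STE12 at -1.04 ± 0.13. For cytosolic ribosomal proteins, with 138 members tested, 5 rose, 55 fell and 78 did not pass (5 rose and 56 fell adjusted over the list alone). Over cytosolic ribosomal proteins the median log2 was -0.30 (camera adjusted p = 2.88e-05, adjusted p = 0.89 with an estimated correlation). RPP0 was at -0.72 ± 0.10 and RPP2B at -0.64 ± 0.10, while RPS28B, whose reads a near-identical copy may share, rose by 1.16 ± 0.15. Purine synthesis genes (17) gave these calls: 1 rose, 11 fell and 5 did not pass (1 rose and 12 fell adjusted over the list alone). Purine synthesis had a median log2 of -0.47 (camera adjusted p = 0.000827, adjusted p = 0.89 with an estimated correlation), led by ADE2 (-1.66 ± 0.07) and SHM2 (-1.46 ± 0.16). The copper list (7 genes) was higher: 5 rose, 1 fell and 1 did not pass (5 rose and 1 fell adjusted over the list alone). For the copper list the median log2 was 0.54 (camera adjusted p = 0.01, adjusted p = 0.89 with an estimated correlation), with CTR1, the copper transporter, at 2.76 ± 0.13. Its call was lost without either library of wild type with CFW (adjusted p up to 0.0821), libraries that enter only through the shared spread. The histone list (10 genes) was called higher: 6 rose, 0 fell and 4 did not pass (7 rose and 0 fell adjusted over the list alone). Over histones the median log2 was 0.29 (camera adjusted p = 0.0246, adjusted p = 0.89 with an estimated correlation), with HTB1 at 0.93 ± 0.11, and this call was lost without mub1, no CFW, replicate 1 (adjusted p 0.0682).

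Without CFW RPN4 was 0.38 ± 0.11 (adjusted p = 0.0197) and UBR2 0.25 ± 0.07 (adjusted p = 0.0182), both past the threshold by edgeR's test and higher in mub1. Leaving out single libraries of the 2 groups raised these adjusted p to at most 0.155 for RPN4 and 0.108 for UBR2. RPN4 lost its call without either wild-type library or mub1 replicate 1 without CFW, and UBR2 without any 1 of the 4. RAD6, the ubiquitin-conjugating partner of Ubr2, did not pass (-0.07 ± 0.07). No proteasome list was called. In the regulatory particle (19S, 19 genes), 8 rose, 0 fell and 11 did not pass (11 rose and 0 fell adjusted over the list alone). The 19S particle had a median log2 of 0.18 (camera adjusted p = 0.308, adjusted p = 0.89 with an estimated correlation). In the core particle (20S, 14 genes), 2 rose, 0 fell and 12 did not pass (2 rose and 0 fell adjusted over the list alone). For the 20S particle the median log2 was 0.10 (camera adjusted p = 0.466, adjusted p = 0.89 with an estimated correlation). Proteasome assembly and regulation (16 genes) gave these calls: 5 rose, 2 fell and 9 did not pass (6 rose and 2 fell adjusted over the list alone). Over proteasome assembly the median log2 was 0.15 (camera adjusted p = 0.371, adjusted p = 0.89 with an estimated correlation). The drug exporter gene PDR5 fell (-2.14 ± 0.13), its regulator PDR3 fell (-0.39 ± 0.11) and PDR1 did not pass (0.00 ± 0.09). The regulator genes YAP1 (0.41 ± 0.08) and CUP9 (0.55 ± 0.10) rose, and HSF1 (0.13 ± 0.10) did not pass. Among cell wall genes PIR3 (1.47 ± 0.33) and GSC2, a glucan synthase subunit (0.80 ± 0.22), rose, whereas SLT2 (-0.27 ± 0.11), RLM1 (0.24 ± 0.11), CHS3 (-0.12 ± 0.10), CRH1 (0.25 ± 0.16) and PST1 (-0.15 ± 0.19) did not pass. The 27 Rlm1 targets gave these calls: 7 rose, 4 fell and 16 did not pass (7 rose and 4 fell adjusted over the list alone). Rlm1 targets had a median log2 of 0.17 (camera adjusted p = 0.846, adjusted p = 0.959 with an estimated correlation). GSC2 lost its call without 1 of 3 libraries (adjusted p up to 0.109) and PDR3 likewise (up to 0.121). In the other direction, SLT2, RLM1 and CRH1 passed without either library of wild type with CFW, replicate 1 or 2, and with only these 4 libraries fitted (adjusted p 0.00482 to 0.00928), and SLT2 with upper-quartile scaling (0.0456). The libraries for GSC2 and PDR3 were wild type, no CFW, replicate 2 and both mub1 libraries without CFW for GSC2, and both wild-type libraries and mub1 replicate 1 without CFW for PDR3.

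CFW in the wild type shows the response to the dye where MUB1 is present. Genes of the cell wall and its signalling were among the largest increases: PIR3, a cell wall protein, rose by 3.16 ± 0.35 or 8.932-fold, KDX1, a kinase-like relative of Slt2, by 2.88 ± 0.16, EXG1, an exoglucanase, by 2.13 ± 0.11, and NCW2 by 2.11 ± 0.21. GRE1 (2.61 ± 0.20) and SIP18 (2.44 ± 0.30), both induced by osmotic stress, CPP3 (2.36 ± 0.23) and PUT4 (2.07 ± 0.31) rose too. Decreases were smaller: IMD2, of guanine nucleotide synthesis (-1.73 ± 0.30), APE1, a vacuolar aminopeptidase (-1.58 ± 0.10), PDR15 (-1.37 ± 0.10), ZPR1 (-1.30 ± 0.29), YJL218W (-1.22 ± 0.12), the chaperone gene SSA4 (-1.20 ± 0.22), the glycogen synthase gene GSY1 (-1.12 ± 0.10) and YHR140W (-1.10 ± 0.15). In total 1134 of 5954 genes changed by edgeR's test, 616 higher and 518 lower, and of the 123 that changed at least 2-fold 107 were higher. Scaled by library totals the split was 716 higher and 321 lower. The libraries of wild type with CFW differed from one another most, with 75.02 times the sampling variance expected from counting against 11.26 to 29.41 in the other groups, and PIR3 had 14178 and 32147 counts in them. The count was 269 without wild type, no CFW, replicate 1 (74% higher), 301 without replicate 2 of that group (70.8% higher), 1788 without wild type, CFW, replicate 1, and 348 with only these 4 libraries in the fit. ZPR1, SSA4 and IMD2 lost their calls without 1 library (highest adjusted p 0.0852, 0.0692 and 0.05001): a wild-type library without CFW for ZPR1 and SSA4, and wild type, CFW, replicate 2 for SSA4 and IMD2. ZPR1 also did so with only these 4 libraries fitted.

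Of 27 targets of Rlm1, the transcription factor of the cell wall integrity pathway, 26 rose, 0 fell and 1 did not pass (27 rose and 0 fell adjusted over the list alone). For Rlm1 targets the median log2 was 1.15 (camera adjusted p = 4.78e-51, adjusted p = 0.354 with an estimated correlation), in the wild-type libraries whose CFW replicates differed most. PRM5 (1.61 ± 0.10), CRH1, a chitin transglycosylase (2.02 ± 0.17), PST1 (1.65 ± 0.19) and CHS3, the main chitin synthase (1.15 ± 0.10), were among them. SLT2, the kinase of that pathway, rose by 1.24 ± 0.11, RLM1 by 0.69 ± 0.11 and GSC2 by 1.15 ± 0.22. GSC2 lost its call without either wild-type library lacking CFW and with only the 4 wild-type libraries fitted (adjusted p up to 0.0780) and RLM1 without wild type, no CFW, replicate 2 (0.0526). Genes of chitin synthesis and crosslinking (17) gave these calls: 10 rose, 0 fell and 7 did not pass (10 rose and 1 fell adjusted over the list alone). Over the chitin list the median log2 was 0.60 (camera adjusted p = 2.12e-09, adjusted p = 0.171 with an estimated correlation), with GFA1 at 1.37 ± 0.12 and PCM1 at 0.75 ± 0.08. For beta-glucan synthesis and remodelling (24 genes), 12 rose, 0 fell and 12 did not pass (13 rose and 0 fell adjusted over the list alone). The beta-glucan list had a median log2 of 0.31 (camera adjusted p = 1.08e-08, adjusted p = 0.171 with an estimated correlation), with KRE6 at 0.68 ± 0.08 and GAS2 at 1.10 ± 0.11. Among 25 cell wall mannoproteins, 14 rose, 1 fell and 10 did not pass (15 rose and 3 fell adjusted over the list alone). For mannoproteins the median log2 was 0.46 (camera adjusted p = 2.78e-08, adjusted p = 0.377 with an estimated correlation), with CIS3 at 0.97 ± 0.13 and SIM1 at 0.60 ± 0.08. The signalling components of the pathway (25 genes) gave these calls: 11 rose, 1 fell and 13 did not pass (13 rose and 1 fell adjusted over the list alone). Over these signalling genes the median log2 was 0.24 (camera adjusted p = 6.82e-05, adjusted p = 0.415 with an estimated correlation), and the phosphatase genes PTP2 (0.90 ± 0.10) and MSG5 (1.03 ± 0.16) rose.

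Further groups changed with CFW in the wild type, again with the spread between the 2 CFW libraries noted above. The list of the G2 to M transition (18 genes) was called higher: 13 rose, 0 fell and 5 did not pass (15 rose and 0 fell adjusted over the list alone). G2 to M genes had a median log2 of 0.54 (camera adjusted p = 4.2e-11, adjusted p = 0.377 with an estimated correlation), with DBF2 at 1.35 ± 0.11 and SWI5 at 0.65 ± 0.09. The mitochondrial ribosomal protein list was called lower: 0 rose, 33 fell and 34 did not pass (0 rose and 41 fell adjusted over the list alone). For mitochondrial ribosomal proteins the median log2 was -0.25 (camera adjusted p = 9.21e-11, adjusted p = 0.377 with an estimated correlation), with MRPL8 at -0.76 ± 0.08. The list of general stress targets of Msn2 and Msn4 (28 genes) was called lower as well: 3 rose, 13 fell and 12 did not pass (3 rose and 16 fell adjusted over the list alone). Over general stress targets the median log2 was -0.38 (camera adjusted p = 2.62e-05, adjusted p = 0.622 with an estimated correlation), with PGM2 at -0.73 ± 0.11 and GSY2 at -0.59 ± 0.10. This call was lost without wild type, CFW, replicate 1 (adjusted p 0.166, with a range from 2.74e-10 over all alternatives). Methionine and sulfur genes (24) gave these calls: 8 rose, 0 fell and 16 did not pass (9 rose and 0 fell adjusted over the list alone). Methionine and sulfur genes had a median log2 of 0.21 (camera adjusted p = 0.000943, adjusted p = 0.377 with an estimated correlation), with MUP1 at 0.81 ± 0.12 and MUP3 at 0.93 ± 0.13. Stationary phase markers (15) gave these calls: 5 rose, 0 fell and 10 did not pass (7 rose and 0 fell adjusted over the list alone). For stationary phase markers the median log2 was 0.36 (camera adjusted p = 7e-05, adjusted p = 0.499 with an estimated correlation), with SED1 at 1.10 ± 0.16. The DNA damage list (15 genes) gave these calls: 7 rose, 1 fell and 7 did not pass (8 rose and 2 fell adjusted over the list alone). Over DNA damage genes the median log2 was 0.34 (camera adjusted p = 0.0091, adjusted p = 0.415 with an estimated correlation), with HUG1 at 1.18 ± 0.15 and RNR3 at 0.67 ± 0.12. The calcineurin list (14 genes) gave these calls: 4 rose, 1 fell and 9 did not pass (4 rose and 1 fell adjusted over the list alone). Calcineurin targets had a median log2 of 0.12 (camera adjusted p = 0.00681, adjusted p = 0.415 with an estimated correlation), with PHO89 at 1.37 ± 0.23. The median of this list ran from 0.01601 to 0.1991 over the alternatives. Of the 15 lists called, the citric acid cycle, glycolysis and 19S proteasome lists were called lower with medians of -0.19, -0.27 and -0.13 (camera adjusted p 0.0356, 0.0439 and 0.046, and adjusted p = 0.745, 0.791 and 0.622 with an estimated correlation). The citric acid cycle call was lost without wild type, no CFW, replicate 2 or CFW, replicate 1 (adjusted p up to 0.171), and the glycolysis call without replicate 2 of either wild-type group and with the 10 CPM filter (0.0876). The 19S call was lost without either library of either group lacking CFW, without wild type, CFW, replicate 1, and with total-count scaling, the 10 CPM filter and the replicate block (0.0893). DNA damage lost its call without wild type, CFW, replicate 2 (0.057) and calcineurin without wild type, no CFW, replicate 2 (0.0602). RPN4 (0.34 ± 0.11), UBR2 (0.01 ± 0.07), RAD6 (0.17 ± 0.07), YAP1 (0.06 ± 0.08), CUP9 (0.19 ± 0.10), HSF1 (-0.18 ± 0.10), PDR1 (-0.13 ± 0.09) and PDR3 (-0.27 ± 0.11) did not pass. PDR5 (-0.45 ± 0.12) and YMR099C (-0.26 ± 0.07) fell, but lost their calls under 9 and 8 alternatives (adjusted p up to 0.191 and 0.177), among them without any 1 wild-type library for PDR5, either mub1 library with CFW for YMR099C and any 1 library without CFW for both. The others were library totals and only the wild-type libraries fitted for both, and limma-voom for PDR5. SRT1 (0.52 ± 0.28) did not pass. Without wild type, CFW, replicate 1 RPN4, CUP9 and PDR3 passed (adjusted p 0.00114, 0.00822 and 0.0233), without replicate 2 HSF1 did (0.0214), and RPN4 passed with DESeq2 (0.0228) and library totals (0.0489).

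**Figure D2:**
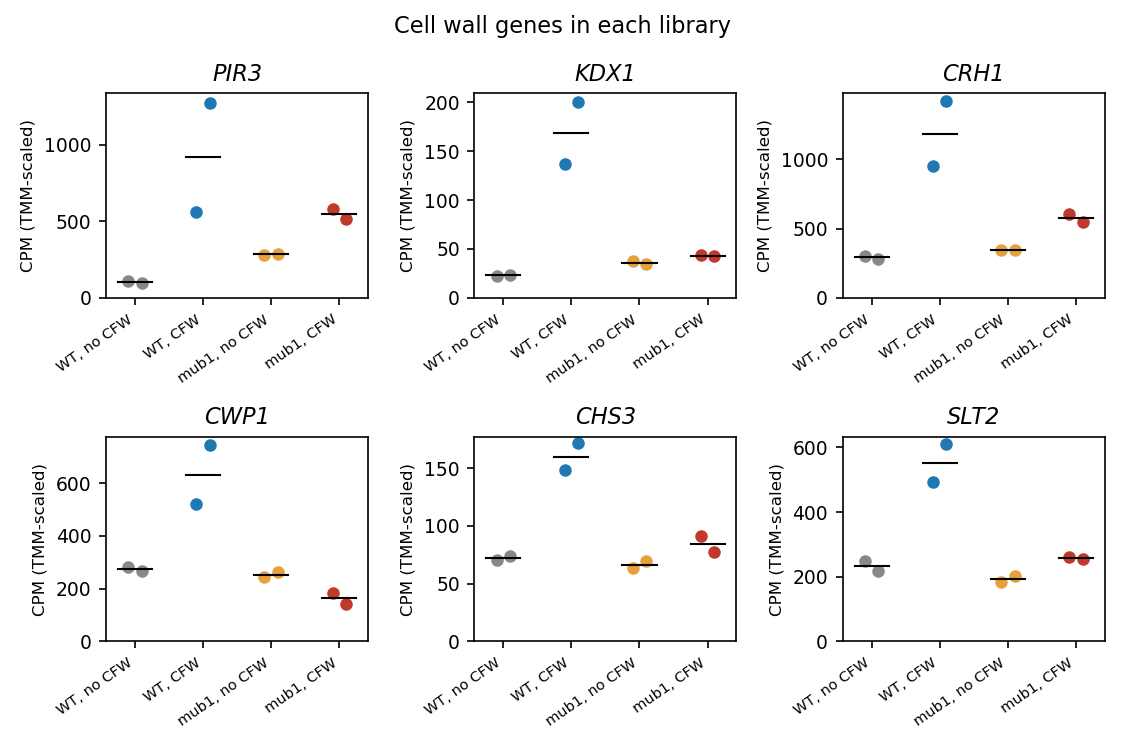
CPM, scaled by TMM factors, of 6 cell wall genes in each library, 1 point per library with the group mean as a line and each axis starting at 0. In the wild type with CFW the mean for CRH1 was 1187 against 292.03 CPM without it, and in mub1 the means were 577 and 347.6 CPM.

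CFW in the mub1 libraries shows the response to the dye where MUB1 is absent. THI4, of thiamine synthesis, rose most (3.53 ± 0.18, or 11.56-fold), followed by CHA1 (2.68 ± 0.12), TDA6 (2.33 ± 0.27), GRE1 (1.96 ± 0.19), SIP18 (1.65 ± 0.28), YDR222W (1.59 ± 0.31), SMP1 (1.5 ± 0.12) and HUG1 (1.49 ± 0.15), which is induced by DNA damage. YOR387C fell most (-4.54 ± 0.19). VHT1, the biotin transporter (-2.43 ± 0.08), and the biotin synthesis genes BIO4 (-2.37 ± 0.12), BIO3 (-2.33 ± 0.16) and BIO2 (-1.80 ± 0.16) fell, as did CTR1 (-1.55 ± 0.13), TIS11, which acts on mRNAs of iron-using proteins (-1.51 ± 0.15), and REG2 (-1.27 ± 0.23). By edgeR's test 1652 of 5954 genes changed, 819 higher and 833 lower, and 72 changed at least 2-fold (41 higher, 31 lower). The split was 1007 higher and 686 lower with upper-quartile scaling, and 1001 and 695 with library totals. With only the mub1 libraries in the fit, 2391 genes changed. The count fell to 531 and 905 without mub1, no CFW, replicate 1 and 2, and to 570 and 678 without mub1, CFW, replicate 1 and 2. It rose to 2536 and 2541 without either library of wild type with CFW, which enter this comparison only through the shared spread. TDA6 lost its call when only these 4 libraries were fitted (adjusted p 0.0736), and YDR222W in that fit and without either library of wild type with CFW (up to 0.16).

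Lists of protein synthesis and metabolism were called in both directions with CFW in mub1. Of 138 cytosolic ribosomal proteins, 40 rose, 0 fell and 98 did not pass (41 rose and 0 fell adjusted over the list alone). For cytosolic ribosomal proteins the median log2 was 0.29 (camera adjusted p = 1.88e-10, adjusted p = 0.735 with an estimated correlation), with RPL38 at 0.66 ± 0.11 and RPP0 at 0.61 ± 0.10. Ribosome biogenesis (49 genes) gave these calls: 27 rose, 0 fell and 22 did not pass (37 rose and 0 fell adjusted over the list alone). Over ribosome biogenesis the median log2 was 0.48 (camera adjusted p = 2.24e-10, adjusted p = 0.735 with an estimated correlation), with CBF5 at 0.66 ± 0.11 and UTP20 at 0.74 ± 0.13. Of 41 amino acid biosynthesis genes under Gcn4, 21 rose, 0 fell and 20 did not pass (26 rose and 0 fell adjusted over the list alone). Amino acid biosynthesis had a median log2 of 0.33 (camera adjusted p = 2.39e-08, adjusted p = 0.595 with an estimated correlation), with HOM3 at 0.89 ± 0.11 and LYS4 at 0.63 ± 0.10. Mitochondrial ribosomal proteins were lower in nearly all members: 0 rose, 63 fell and 4 did not pass (0 rose and 65 fell adjusted over the list alone). For mitochondrial ribosomal proteins the median log2 was -0.43 (camera adjusted p = 2.97e-25, adjusted p = 0.592 with an estimated correlation), with MRPL13 at -0.65 ± 0.07. The respiratory chain list was lower too: 0 rose, 10 fell and 23 did not pass (0 rose and 12 fell adjusted over the list alone). Over the respiratory chain the median log2 was -0.29 (camera adjusted p = 0.000244, adjusted p = 0.735 with an estimated correlation), with CYT1 at -0.44 ± 0.11. So was the citric acid cycle: 2 rose, 13 fell and 5 did not pass (2 rose and 13 fell adjusted over the list alone). The citric acid cycle had a median log2 of -0.46 (camera adjusted p = 0.000258, adjusted p = 0.595 with an estimated correlation), with LSC2 at -0.74 ± 0.10. In the iron regulon (26 genes) 0 rose, 10 fell and 16 did not pass (0 rose and 10 fell adjusted over the list alone). For the iron regulon the median log2 was -0.17 (camera adjusted p = 0.000525, adjusted p = 0.595 with an estimated correlation), with FIT2 at -1.10 ± 0.13 and FTR1 at -0.75 ± 0.12. General stress targets gave these calls: 2 rose, 11 fell and 15 did not pass (2 rose and 11 fell adjusted over the list alone). Over general stress targets the median log2 was -0.28 (camera adjusted p = 0.00057, adjusted p = 0.735 with an estimated correlation), with PGM2 at -0.99 ± 0.11. Autophagy genes (22) gave these calls: 1 rose, 10 fell and 11 did not pass (1 rose and 13 fell adjusted over the list alone). Autophagy had a median log2 of -0.29 (camera adjusted p = 0.000638, adjusted p = 0.735 with an estimated correlation), with ATG19 at -0.54 ± 0.06.

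Of the cell wall lists, the Rlm1 targets alone were called with CFW in mub1. These 27 genes gave these calls: 9 rose, 1 fell and 17 did not pass (13 rose and 1 fell adjusted over the list alone). For Rlm1 targets the median log2 was 0.28 (camera adjusted p = 0.00076, adjusted p = 0.735 with an estimated correlation), with PRM5 at 1.03 ± 0.10 and CHS1 at 0.77 ± 0.10. SLT2 (0.42 ± 0.11), CHS3 (0.34 ± 0.10) and CRH1 (0.73 ± 0.16) passed, and RLM1 (-0.02 ± 0.11), GSC2 (0.06 ± 0.21), PIR3 (0.95 ± 0.33) and PST1 (0.57 ± 0.19) did not. Leaving out single libraries raised the adjusted p of SLT2 to 0.168, of CHS3 to 0.242 and of CRH1 to 0.0833. For SLT2 this held for all 4 mub1 libraries, for CRH1 for all but mub1, CFW, replicate 2, and for CHS3 for both libraries of wild type without CFW and the same 3. The chitin list (17 genes) was not called: 6 rose, 1 fell and 10 did not pass (6 rose and 2 fell adjusted over the list alone). Over the chitin list the median log2 was 0.11 (camera adjusted p = 0.171, adjusted p = 0.645 with an estimated correlation). The beta-glucan list was not called either: 6 rose, 1 fell and 17 did not pass (6 rose and 2 fell adjusted over the list alone). The beta-glucan list had a median log2 of 0.07 (camera adjusted p = 0.114, adjusted p = 0.595 with an estimated correlation). Nor was the mannoprotein list: 4 rose, 1 fell and 20 did not pass (4 rose and 1 fell adjusted over the list alone). For mannoproteins the median log2 was 0.12 (camera adjusted p = 0.171, adjusted p = 0.735 with an estimated correlation). Nor were the signalling components: 2 rose, 0 fell and 23 did not pass (0 rose and 0 fell adjusted over the list alone). Over these signalling genes the median log2 was -0.01 (camera adjusted p = 0.829, adjusted p = 0.951 with an estimated correlation). The G2 to M list was called higher: 10 rose, 0 fell and 8 did not pass (13 rose and 0 fell adjusted over the list alone). G2 to M genes had a median log2 of 0.41 (camera adjusted p = 5e-06, adjusted p = 0.595 with an estimated correlation), with SWI5 at 0.68 ± 0.09 and ALK1 at 0.74 ± 0.10. So was the methionine and sulfur list: 12 rose, 0 fell and 12 did not pass (13 rose and 0 fell adjusted over the list alone). For methionine and sulfur genes the median log2 was 0.32 (camera adjusted p = 6.32e-05, adjusted p = 0.592 with an estimated correlation), with STR3 at 1.03 ± 0.12. RPN4 (0.21 ± 0.11), UBR2 (0.04 ± 0.07), RAD6 (0.22 ± 0.07), YAP1 (0.20 ± 0.08), CUP9 (0.02 ± 0.10), HSF1 (-0.18 ± 0.10), PDR1 (0.23 ± 0.09), PDR3 (0.21 ± 0.11) and SRT1 (0.00 ± 0.27) did not pass. PDR5 rose (0.38 ± 0.12) and YMR099C fell (-0.21 ± 0.07), calls lost under 8 and 10 alternatives (adjusted p up to 0.382 and 0.266), among them without any 1 library lacking CFW and without mub1, CFW, replicate 1 for both, wild type, CFW, replicate 2 for PDR5 and mub1, CFW, replicate 2 for YMR099C. The replicate block lost both as well, only the mub1 libraries fitted lost PDR5, and upper-quartile scaling, library totals and no low-count filter lost YMR099C. Without either library of wild type with CFW, RPN4, RAD6, YAP1, PIR3 and PST1 passed (adjusted p up to 0.0412, 0.0314, 0.0185, 2.28e-06 and 0.000162). PDR1 passed without replicate 2 of that group (0.0454) and without mub1, no CFW, replicate 1 (0.0445). PST1 also passed with DESeq2, limma-voom, the replicate block, library totals, upper-quartile scaling and only the mub1 libraries fitted (adjusted p 0.00821, 0.0323, 0.0468, 0.048, 0.0381 and 0.000375). PIR3 did with limma-voom, the 10 CPM filter, upper-quartile scaling and only the mub1 libraries (0.0423, 0.0479, 0.0459 and 9.13e-06). RAD6 did with library totals, the 10 CPM filter, upper-quartile scaling and only the mub1 libraries (up to 0.0471), YAP1 with upper-quartile scaling and only the mub1 libraries (up to 0.0362) and PDR1 with upper-quartile scaling (0.0498). The 19S list gave these calls: 0 rose, 0 fell and 19 did not pass (0 rose and 0 fell adjusted over the list alone). Over the 19S particle the median log2 was -0.01 (camera adjusted p = 0.996, adjusted p = 0.998 with an estimated correlation). In all, 19 of 49 lists were called, 10 up and 9 down. The stationary phase list was called up although its median was -0.05 and its mean 0.25 (camera adjusted p 0.0397, adjusted p = 0.735 with an estimated correlation). It lost its call without either library of wild type with CFW, mub1, no CFW, replicate 2 or mub1, CFW, replicate 1, and with total-count scaling or the 10 CPM filter (adjusted p up to 0.324).

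**Figure D3:**
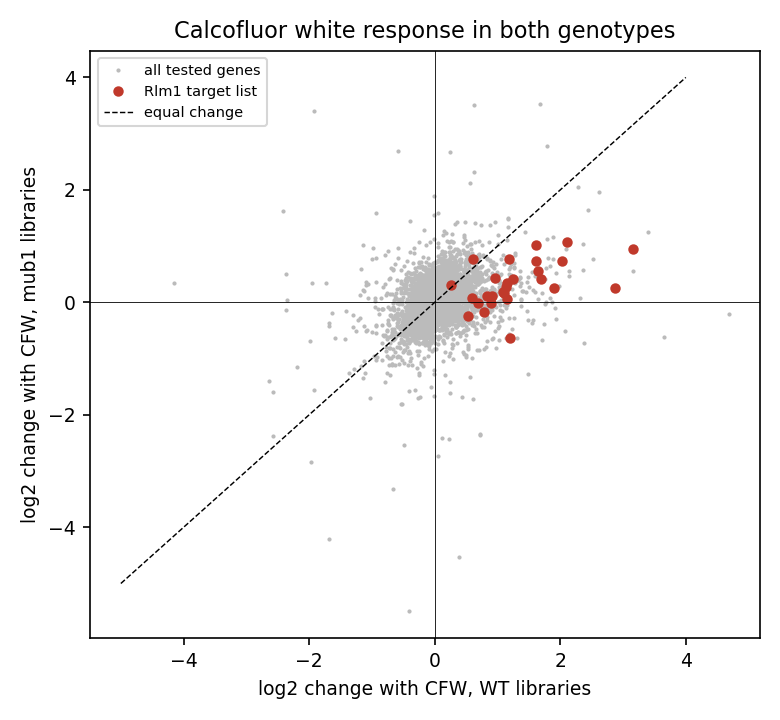
The log2 change with CFW in the mub1 libraries against that in the wild-type libraries for 5954 tested genes (grey) and the Rlm1 target list (red), with the line of equal change dashed. Over the Rlm1 targets the median was 1.15 in the wild type and 0.28 in mub1.

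Under CFW the genotypes were compared with each other to see what distinguishes the stressed cells. URA3, MET17 and LEU2 again led the increases in mub1, followed by GAP1 (5.32 ± 0.14), MEP2 (4.27 ± 0.13), YHB1, the nitric oxide dioxygenase (3.45 ± 0.22), DAL3, of allantoin use (3.15 ± 0.17), and ARO9, of aromatic amino acid breakdown (2.95 ± 0.13). TRP1 and MUB1 led the decreases, before SPL2 (-5.07 ± 0.29), PHO5 (-3.99 ± 0.19), LEU1 (-3.04 ± 0.14), QDR2 (-2.94 ± 0.09), PHO12, whose reads the near-identical PHO11 may share (-2.79 ± 0.27), and OAC1 (-2.54 ± 0.17). By edgeR's test 2138 of 5954 genes changed, 1110 higher and 1028 lower, and 246 changed at least 2-fold (142 higher, 104 lower). All 16 of these genes kept their calls under every alternative run. The 4 marker genes part these libraries as MUB1 does, and the count was 1274 and 1283 without mub1, CFW, replicate 1 and 2, and 1419 with only these 4 libraries in the fit.

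Several cell wall lists were called lower in mub1 under CFW, in libraries that also differed in the 4 marker genes and against the wild-type pair with the widest spread. Of 27 Rlm1 targets, 2 rose, 22 fell and 3 did not pass (2 rose and 22 fell adjusted over the list alone). Rlm1 targets had a median log2 of -0.85 (camera adjusted p = 1.41e-11, adjusted p = 0.55 with an estimated correlation), with KDX1 at -1.96 ± 0.15, CWP1, a cell wall mannoprotein, at -1.95 ± 0.17 and PRM5 at -1.80 ± 0.10. SLT2 (-1.10 ± 0.11), RLM1 (-0.46 ± 0.11), CHS3 (-0.92 ± 0.10), CRH1 (-1.04 ± 0.16) and PST1 (-1.23 ± 0.19) were lower, and PIR3 (-0.75 ± 0.32) and GSC2 (-0.29 ± 0.21) did not pass. RLM1 lost its call without either mub1 library with CFW (adjusted p up to 0.0679), and PIR3 and GSC2 passed without wild type, CFW, replicate 1 (1.12e-07 and 2.8e-05). In the mannoprotein list 1 rose, 14 fell and 10 did not pass (2 rose and 14 fell adjusted over the list alone). For mannoproteins the median log2 was -0.53 (camera adjusted p = 8.98e-05, adjusted p = 0.481 with an estimated correlation), with CIS3 at -1.31 ± 0.13 and HSP150 at -1.38 ± 0.15. In the chitin list 1 rose, 9 fell and 7 did not pass (1 rose and 9 fell adjusted over the list alone). Over the chitin list the median log2 was -0.44 (camera adjusted p = 0.00473, adjusted p = 0.453 with an estimated correlation), with SKT5 at -0.87 ± 0.10 and CHS7 at -0.94 ± 0.11. In the beta-glucan list 1 rose, 11 fell and 12 did not pass (3 rose and 11 fell adjusted over the list alone). The beta-glucan list had a median log2 of -0.20 (camera adjusted p = 0.00689, adjusted p = 0.453 with an estimated correlation), with EXG1 at -1.36 ± 0.11 and GAS2 at -1.67 ± 0.11. The unfolded protein response list (20 genes) was lower: 0 rose, 13 fell and 7 did not pass (0 rose and 13 fell adjusted over the list alone). For the unfolded protein response the median log2 was -0.26 (camera adjusted p = 0.00689, adjusted p = 0.453 with an estimated correlation), with SCJ1 at -0.76 ± 0.09. So was the G2 to M list: 0 rose, 8 fell and 10 did not pass (0 rose and 9 fell adjusted over the list alone). Over G2 to M genes the median log2 was -0.23 (camera adjusted p = 0.00753, adjusted p = 0.757 with an estimated correlation), with DBF2 at -0.83 ± 0.11.

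The proteasome lists were called higher in mub1 under CFW, by small amounts and with the same marker differences. In the 19S list 14 rose, 0 fell and 5 did not pass (16 rose and 0 fell adjusted over the list alone). The 19S particle had a median log2 of 0.32 (camera adjusted p = 0.00541, adjusted p = 0.55 with an estimated correlation), with RPT6 at 0.53 ± 0.08 and RPN9 at 0.39 ± 0.06. In the 20S list 12 rose, 0 fell and 2 did not pass (13 rose and 0 fell adjusted over the list alone). For the 20S particle the median log2 was 0.29 (camera adjusted p = 0.00689, adjusted p = 0.453 with an estimated correlation), with PRE4 at 0.48 ± 0.07 and PRE7 at 0.44 ± 0.07. In the assembly list 10 rose, 0 fell and 6 did not pass (10 rose and 0 fell adjusted over the list alone). Over proteasome assembly the median log2 was 0.23 (camera adjusted p = 0.0385, adjusted p = 0.453 with an estimated correlation), with ECM29 at 0.74 ± 0.07 and UMP1 at 0.45 ± 0.07. The assembly call was lost without either wild-type library lacking CFW, mub1, no CFW, replicate 2 or mub1, CFW, replicate 2, and with the replicate block (adjusted p 0.0518 to 0.0576). RPN4 itself did not pass (0.25 ± 0.11, adjusted p = 0.107 by edgeR's test). It passed without wild type, CFW, replicate 2, with an adjusted p of 0.00396, as did HSF1 with 0.0275. UBR2 was higher (0.27 ± 0.07), and RAD6 did not pass (-0.02 ± 0.07). YAP1 (0.55 ± 0.08), CUP9 (0.38 ± 0.10) and PDR1 (0.35 ± 0.09) were higher, PDR5 was lower (-1.31 ± 0.13), and PDR3 (0.09 ± 0.10) and HSF1 (0.13 ± 0.10) did not pass. UBR2, CUP9 and PDR1 lost their calls without either mub1 library with CFW, and UBR2 and CUP9 also with only the 4 libraries compared (adjusted p up to 0.0846, 0.0739 and 0.0838). ADE2, of purine synthesis (-1.91 ± 0.07), and HIS3, of histidine synthesis (-0.73 ± 0.08), were lower, and YMR099C (-0.10 ± 0.07) and SRT1 (0.05 ± 0.27) did not pass.

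Metabolic groups also differed between the genotypes under CFW, and the marker genes LEU2, URA3, MET17 and TRP1 differed alongside. Amino acid biosynthesis genes were higher: 26 rose, 4 fell and 11 did not pass (27 rose and 4 fell adjusted over the list alone). Amino acid biosynthesis had a median log2 of 0.52 (camera adjusted p = 7.92e-09, adjusted p = 0.558 with an estimated correlation), with ARG8 at 1.78 ± 0.07 and ASN1 at 1.76 ± 0.10 and with LEU1 lower. Mitochondrial ribosomal proteins were higher: 50 rose, 0 fell and 17 did not pass (51 rose and 0 fell adjusted over the list alone). For mitochondrial ribosomal proteins the median log2 was 0.41 (camera adjusted p = 1.89e-09, adjusted p = 0.453 with an estimated correlation), with MRPL11 at 0.79 ± 0.07. The respiratory chain list gave these calls: 29 rose, 1 fell and 3 did not pass (30 rose and 1 fell adjusted over the list alone). Over the respiratory chain the median log2 was 0.53 (camera adjusted p = 2.5e-09, adjusted p = 0.647 with an estimated correlation), with CYC1 at 2.94 ± 0.10. The ergosterol list gave these calls: 16 rose, 3 fell and 6 did not pass (17 rose and 3 fell adjusted over the list alone). Ergosterol synthesis had a median log2 of 0.49 (camera adjusted p = 1.78e-05, adjusted p = 0.55 with an estimated correlation), with HMG1 at 1.56 ± 0.10. The phosphate regulon was lower: 3 rose, 11 fell and 3 did not pass (3 rose and 11 fell adjusted over the list alone). For the phosphate regulon the median log2 was -0.70 (camera adjusted p = 7.92e-09, adjusted p = 0.453 with an estimated correlation), with PHO84 at -2.48 ± 0.09. All a-cell markers were lower again: 0 rose, 7 fell and 0 did not pass (0 rose and 7 fell adjusted over the list alone). Over a-cell markers the median log2 was -1.05 (camera adjusted p = 2.14e-05, adjusted p = 0.481 with an estimated correlation), with MFA1 at -2.01 ± 0.19. Purine genes gave these calls: 3 rose, 9 fell and 5 did not pass (3 rose and 10 fell adjusted over the list alone). Purine synthesis had a median log2 of -0.44 (camera adjusted p = 0.00159, adjusted p = 0.558 with an estimated correlation), with ADE2 at -1.91 ± 0.07 and SHM2 at -1.89 ± 0.16, a call lost without wild type, CFW, replicate 1 (adjusted p 0.177). Ribosome biogenesis was called higher (median log2 0.23, camera adjusted p = 0.0361, adjusted p = 0.934 with an estimated correlation). That call was lost without wild type, CFW, replicate 2 or mub1, CFW, replicate 1, and the median ran from 0.01441 to 0.5097 over the alternatives.

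Whether the genotype effect was the same in both media was asked across genes, which are not independent replicates. Over 5954 genes the log2 differences between genotypes without and with CFW had a Pearson r of 0.768 and a Spearman rho of 0.61, from comparisons that share no library, against r = 0.0578 in data simulated with no effect. Both comparisons called 746 genes higher in mub1, where independent lists would share 245.3, and 602 genes lower, where they would share 213.7, and 27 genes in opposite directions. Without the 6 genes absent in one genotype r was 0.6693. For the CFW effect in the 2 genotypes r was 0.3397 and rho 0.4035, against r = -0.0164 with no effect. Leaving out 1 library at a time moved this r to between 0.1816 and 0.37. Here 236 genes rose in both genotypes against 84.73 for independent lists, 281 fell in both against 72.47, and 24 were called in opposite directions.

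The interaction tests for each gene whether its CFW response differed between the genotypes. The response in mub1 was lower than in the wild type for YOR387C (-4.93 ± 0.28), BIO4 (-3.10 ± 0.17), BIO3 (-3.06 ± 0.23), VHT1 (-2.65 ± 0.12), KDX1 (-2.62 ± 0.22) and PUT4 (-2.58 ± 0.38). It was higher for CHA1 (2.43 ± 0.15), THI4 (1.86 ± 0.27), ADH1, the main alcohol dehydrogenase (1.21 ± 0.26), RMA1 (1.14 ± 0.19), CTT1, the cytosolic catalase (1.12 ± 0.19), and PDR12, a weak acid exporter (1.06 ± 0.18). Of 5954 genes, 149 passed by edgeR's test, 53 with a higher and 96 with a lower response in mub1, and 50 differed at least 2-fold (9 higher, 41 lower). Single libraries moved this count widely. It was 10 and 9 without wild type, no CFW, replicate 1 and 2, 16 and 49 without mub1, no CFW, replicate 1 and 2, and 30 and 11 without mub1, CFW, replicate 1 and 2. It was 1779 and 366 without wild type, CFW, replicate 1 and 2, the pair with the widest spread. DESeq2 called 557. Of the 12 genes named, 6 lost their calls without at least 1 library: THI4, ADH1, RMA1, CTT1, PDR12 and PUT4, with adjusted p up to 0.111, 0.206, 0.12, 0.125, 0.123 and 0.111. Each did so without either wild-type library lacking CFW, without mub1, no CFW, replicate 1 and without mub1, CFW, replicate 2. All but RMA1 also did so without mub1, CFW, replicate 1, RMA1 without mub1, no CFW, replicate 2, and ADH1 with upper-quartile scaling, the 10 CPM filter, the replicate block and limma-voom.

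Rlm1 targets were the list with the lowest p for the interaction, in libraries that differ in the marker genes. Of 27 targets 0 rose, 9 fell and 18 did not pass (0 rose and 25 fell adjusted over the list alone). For Rlm1 targets the median log2 was -0.86 (camera adjusted p = 2.69e-24, adjusted p = 0.525 with an estimated correlation), where rose and fell stand for a higher or lower response in mub1. KDX1, CWP1 (-1.83 ± 0.23), CRG1 (-1.63 ± 0.24), PTP2 (-0.92 ± 0.15), CHS3 (-0.81 ± 0.14), CRH1 (-1.29 ± 0.23) and SLT2 (-0.82 ± 0.16) passed, and RLM1 (-0.70 ± 0.16), PIR3 (-2.21 ± 0.46), GSC2 (-1.09 ± 0.30) and PST1 (-1.08 ± 0.27) did not. RLM1, PIR3, GSC2 and PST1 passed with DESeq2 and without either library of wild type with CFW (adjusted p up to 0.0104, 0.00409, 0.00661 and 0.00731). RLM1 also passed with RLE scaling and no low-count filter (0.0492 and 0.0456), and PIR3 with the 10 CPM filter and limma-voom (0.045 and 0.0492). SLT2 and CRH1 lost their calls without any 1 of the 6 libraries outside that group, and CHS3 without any of these but mub1, CFW, replicate 1 (adjusted p up to 0.178, 0.141 and 0.134). SLT2 also did so with the replicate block. The chitin list gave these calls: 0 rose, 4 fell and 13 did not pass (0 rose and 8 fell adjusted over the list alone). Over the chitin list the median log2 was -0.25 (camera adjusted p = 0.000146, adjusted p = 0.404 with an estimated correlation), led by GFA1 (-1.33 ± 0.16). The mannoprotein list gave these calls: 1 rose, 3 fell and 21 did not pass (5 rose and 13 fell adjusted over the list alone). Mannoproteins had a median log2 of -0.43 (camera adjusted p = 0.000543, adjusted p = 0.664 with an estimated correlation). The beta-glucan list gave these calls: 0 rose, 2 fell and 22 did not pass (0 rose and 5 fell adjusted over the list alone). For the beta-glucan list the median log2 was -0.21 (camera adjusted p = 0.000914, adjusted p = 0.404 with an estimated correlation), with EXG1 at -1.57 ± 0.15. Some lists were called higher with few single calls. Amino acid biosynthesis gave these calls: 2 rose, 0 fell and 39 did not pass (21 rose and 0 fell adjusted over the list alone). Over amino acid biosynthesis the median log2 was 0.40 (camera adjusted p = 1.32e-10, adjusted p = 0.664 with an estimated correlation), with ILV2 at 0.97 ± 0.17 and HOM3 at 0.74 ± 0.16. Ribosome biogenesis gave these calls: 0 rose, 0 fell and 49 did not pass (8 rose and 0 fell adjusted over the list alone). Ribosome biogenesis had a median log2 of 0.43 (camera adjusted p = 9.04e-10, adjusted p = 0.664 with an estimated correlation). PDR5, the drug exporter gene, had a higher response in mub1 (0.83 ± 0.17), though its call was lost under 9 alternatives (adjusted p up to 0.18), namely without any 1 library lacking CFW, without wild type, CFW, replicate 2, without mub1, CFW, replicate 1, and with the replicate block, library totals and limma-voom. RPN4 (-0.13 ± 0.16), UBR2 (0.03 ± 0.10), RAD6 (0.05 ± 0.10), YAP1 (0.15 ± 0.11), CUP9 (-0.17 ± 0.14), HSF1 (0.00 ± 0.14), PDR1 (0.36 ± 0.13) and PDR3 (0.48 ± 0.15) did not pass, though CUP9 and PDR3 did without wild type, CFW, replicate 1 (adjusted p 0.0416 and 0.00839). The marker gene HIS3 rose with CFW in mub1 (0.63 ± 0.09) but did not pass in the wild type (-0.26 ± 0.08), and its higher response in mub1 passed (0.89 ± 0.12). That last call was lost without either wild-type library lacking CFW, without mub1, no CFW, replicate 1 and without mub1, CFW, replicate 2 (adjusted p up to 0.0962). In the wild type HIS3 passed with limma-voom (0.046) and without wild type, CFW, replicate 1 (0.0115). In all 21 of 49 lists were called, 7 up and 14 down, and none with an estimated correlation, where 5 had an unadjusted p under 0.05.

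**Figure D4:**
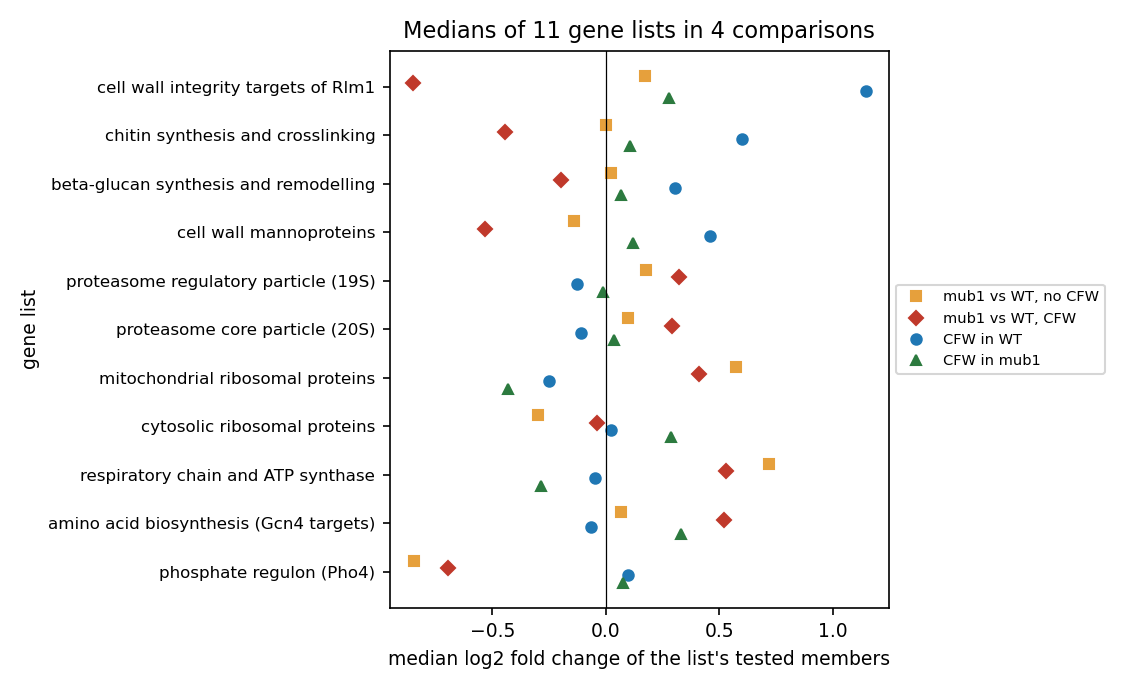
Median log2 fold change of the tested members of 11 gene lists in the 4 comparisons of 2 groups, 1 marker shape per comparison. The Rlm1 targets lay at 1.15 with CFW in the wild type and at -0.85 for mub1 against wild type with CFW, and the mitochondrial ribosomal proteins at 0.57 and 0.41 for the genotype and at -0.25 and -0.43 for CFW.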

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

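All tests of explanations in this part were chosen after the results they measure had been seen, whereas the interaction tests were planned. The Calcofluor response differed between the genotypes, by the test of the interaction, for 149 genes, and the log2 differences of those named by the rule, by the gene lists or in the groups below follow (response in mub1 minus response in wild type). The lower ones were YOR387C -4.93, BIO4 -3.10, BIO3 -3.06, VHT1 -2.65, BIO5 -1.60 and BIO2 -1.26, the last 5 of biotin use. Cell wall genes among them were KDX1 -2.62, CWP1 -1.83, CRG1 -1.63, EXG1 -1.57, GFA1 -1.33, CRH1 -1.29, PTP2 -0.92, SLT2 -0.82, CHS3 -0.81, SIM1 -0.70, PCM1 -0.65, SRL1 -0.57, SCW11 -0.51 and DSE4 -0.71. Metal and phosphate genes were TIS11 -1.46, CTR1 -1.23, FTR1 -1.05, FRE1 -0.64, VEL1 -1.30, PHO5 -1.20 and PHO84 -0.63. The rest were PUT4 -2.58, ASH1 -1.35, ALD4 -0.83, DBF2 -0.79, SIL1 -0.73, HHF1 -0.62, FPR2 -0.56, ROX1 -0.56, RSM10 -0.48 and ATG19 -0.45. Higher ones were CHA1 2.43, THI4 1.86, ADH1 1.21, RMA1 1.14, CTT1 1.12, PDR12 1.06, ILV2 0.97, APE1 0.96, TIR3 0.96, YJL218W 0.90, HIS3 0.89, CMK2 0.87, PDR5 0.83, HOM3 0.74, QDR2 0.66, HMG1 0.61 and CRZ1 0.56.

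By camera with the preset correlation 21 lists differed in their response, and none did with an estimated correlation (lowest adjusted p 0.404). Lower medians in mub1 were those of Rlm1 targets (-0.86), gluconeogenesis (-0.59), mannoproteins (-0.43), copper (-0.32), autophagy (-0.32), the unfolded protein response (-0.28), chitin (-0.25), iron (-0.24), cell wall signalling (-0.24), beta-glucan (-0.21), the respiratory chain (-0.21), daughter cell separation (-0.20), histones (-0.17) and mitochondrial ribosomal proteins (-0.16). Higher medians were those of heat shock targets (0.44), ribosome biogenesis (0.43), amino acid biosynthesis (0.40), cytosolic ribosomal proteins (0.28), Pdr1 and Pdr3 targets (0.25), the 20S proteasome (0.19) and ergosterol synthesis (0.16). Calls of 6 of these lists were lost without a single library. For the respiratory chain this was wild type with Calcofluor, replicate 2, mub1 without it, replicate 1, or mub1 with it, replicate 2 (adjusted p up to 0.461). Histones lost theirs without wild type with Calcofluor, replicate 1, mub1 without it, replicate 1, or mub1 with it, replicate 2 (0.101). Ergosterol synthesis did without wild type with Calcofluor, replicate 2, or mub1 without it, replicate 1 (0.161). Copper and the 20S proteasome did without wild type with Calcofluor, replicate 1 (0.0541 and 0.0721). Pdr1 and Pdr3 targets did with the replicate block and without replicate 1 of any group (0.378).

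The weaker rise of the Rlm1 targets in mub1 was weighed first. The median difference in response over the list was -0.864 on the log2 scale. A single deviating library among the 2 of wild type with Calcofluor is argued against: without either of them the median nearest 0 was -0.655 and the list stayed past the threshold at the preset correlation. With an estimated correlation the list was not called for the interaction even with all libraries (adjusted p 0.525). Over all 8 libraries left out in turn the median ran from -1.076 to -0.655, with a highest adjusted p of 2.06e-20 at the preset correlation. A level already raised in mub1 before the dye is argued against as the whole cause: the median genotype difference without Calcofluor was 0.1746 (95% bootstrap interval over genes -0.1234 to 0.2515), smaller than the difference in response. That interval treats the genes as independent, although their estimated correlation was 0.8, and holds no spread between libraries, so it understates the uncertainty. Without its 4 strongest risers in the wild type the median was -0.8244. Different parent strains remain open: 0 marker patterns occur with both states of MUB1, so a loss of MUB1 and a difference of parents cannot be told apart for these targets.

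The marker genes were weighed next. Besides MUB1, 5 genes had at most 3 counts in every library of one genotype and at least 100 in every library of the other: LEU2, URA3, MET17, TRP1 and SOR2. The labels name strain BMA41 for both genotypes. A derivation of the mub1 strain from the other by 1 gene replacement allows at most 1 such gene, so the 5 found argue against it. Of these, 4 (LEU2, URA3, MET17 and SOR2) were absent from the libraries labelled wild type, and TRP1 from those labelled mub1. An exchange of single libraries between the genotypes is argued against: MUB1 had at most 1 count in each library labelled mub1. Different parents of the 2 genotypes stay open: the marker genes raised the question and cannot answer it, and only 1 further gene was absent (SOR2, which has a near-identical copy, SOR1). An exchange of all 4 libraries of each genotype would leave MUB1 present in the libraries labelled mub1, which was not seen. In every genotype comparison of the report, the marker genes and MUB1 change together.

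Ribosomal protein genes with few counts were weighed last, a pattern in the counting and not between the groups. Of 138 such genes (median 17291 counts), 7 had a mean under 1000 counts: RPL39, RPL43A, RPL22A, RPL36B, RPS11B, RPL33A and RPL28. Loss of reads shared by near-identical copies is argued against as the whole cause, since 2 of them (RPL28 and RPL39) have no second copy in the table. Of the 7, 5 have next to them, on the other strand, an identifier that RefSeq does not list, against 10 of the 131 others (Fisher exact p = 0.000143). Reads over opposite-strand genes may therefore have been left uncounted, as a count without regard to strand would do, and levels of overlapping genes may be too low. The design gives no biological explanation to test for this pattern.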

How the results depend on the processing

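Removing the genes absent in one genotype and removing the 4 strongest risers from the Rlm1 list were chosen after seeing the data; all other alternatives were fixed beforehand, and each was run for the results it was fixed for. Lists and correlations were not run with upper-quartile scaling, DESeq2, limma-voom or only the groups compared. No result changed its direction past the threshold under the alternatives run for it. With RLE, upper-quartile or total-count scaling, limma-voom and both low-count filters, each total of changed genes stayed within 1.5 times the reported one, but the split by direction moved: with library totals 716 genes were higher and 321 lower for Calcofluor in wild type (69% higher, from 54.3%) and 1001 and 695 in mub1. Upper-quartile scaling gave 1007 and 686 in mub1, and 1209 and 1428 for the genotype without Calcofluor.

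Fitting the replicate number as a block gave 92 genes for the interaction (32 higher, 60 lower, 86 shared with the 149), and replicate numbers correlated weakly across groups (-0.161 to 0.168). With only the groups compared, 1419 genes differed between genotypes with Calcofluor and 348 changed with Calcofluor in the wild type. DESeq2 called 557 for the interaction, including all 149. Demanding a 2-fold change left 278 and 246 genes for the genotype without and with Calcofluor, 123 and 72 for Calcofluor in wild type and mub1, and 50 for the interaction. With an estimated correlation 0 lists were called in each of the 5 comparisons, and 2, 3, 5, 2 and 5 had an unadjusted p under 0.05. The correlation of the genotype effect was 0.5516 without a low-count filter, 0.8266 with at least 10 CPM and 0.6693 without the absent genes, and that of the Calcofluor effect 0.2331 and 0.4202 with those 2 filters. The cause was not tested, except that a larger required change makes fewer calls by construction.

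Leaving out 1 library at a time leaves a group with 1 library, which is assumed to vary like the other groups. The counts then ran from 1440 to 3223 for the genotype without Calcofluor, 1274 to 2502 with it, 269 to 1788 for Calcofluor in wild type, 531 to 2541 in mub1 and 9 to 1779 for the interaction. Lists called ran from 10 to 14, 18 to 22, 11 to 22, 18 to 21 and 17 to 24. The correlations ran from 0.6378 to 0.7411 and from 0.1816 to 0.37. Depth sets a floor of 0.0947 to 0.124 CPM per library. In simulated data with 2 libraries per group and these depths 42% of interactions of 0.5 log2 were recovered.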

Other observations

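All tests in this part but that of the planned Zap1 list were chosen after the results were seen. A hypothesis from the marker genes is that the libraries labelled wild type lack LEU2 and URA3 and those labelled mub1 do not, with effects beyond the markers. Targets of Leu3, the regulator of leucine synthesis (8 genes), had a median genotype difference of -0.9336 without Calcofluor and -0.7508 with it, with 6 and 5 lower and 1 and 2 higher in mub1. Targets of Ppr1, the regulator of uracil synthesis (3 genes), had medians of -1.586 and -1.409, and 2 were lower in each medium, while 1 was higher without Calcofluor and 0 with it. Targets of Hap1, a regulator of respiratory and sterol genes (12 genes), had medians of 0.7923 and 0.7438, and 9 and 8 were higher. Leu3 and Hap1 came to mind after some of their targets had been seen among the leading genes. The medians of the other targets were -0.4919 and 0.2836 for Leu3 (5 genes) and 0.6921 and 0.2551 for Hap1 (7 genes), without and with Calcofluor. Against 10000 random lists of like expression these lay at percentiles 0.8 and 91.86 for Leu3 and 99.9 and 93.12 for Hap1, so they stood apart without Calcofluor but not with it. Leaving out the leading members moves a median towards 0 or past it, so the result with Calcofluor does not show a weaker difference there. Loss of LEU2 and a more active HAP1 allele stay open as causes. The Ppr1 list leaves out URA3 itself, which led the named genes, and no gene in the list had been named. The medians of that list lay at percentiles 0 and 0.02, so loss of URA3 may account for the lower uracil genes, though the list holds 3 genes. Only the count table was used, and the sequence of these genes was not examined.

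Some groups of genes were put together after their values were seen. Of 11 genes under nitrogen catabolite repression (GAP1, MEP2, PUT4, DAL80, DAL1, DAL2, DAL3, DAL4, DAL5, DAL7 and UGA4), 10 were higher in mub1 without Calcofluor (median 1.503) and 9 with it (median 1.03). Of 5 genes of biotin synthesis and uptake, 5 were higher in mub1 without Calcofluor (median 3.19) and 2 with it (median 0.39). With Calcofluor all 5 fell in mub1 (median -2.33), while in the wild type 3 rose and 1 fell. ADH4, a gene linked to zinc shortage, had 125321 and 130071 counts in the mub1 libraries without Calcofluor, 3253 and 28532 with it, and 1589 to 2703 in the libraries labelled wild type. ZPS1, of the same kind, had 43668 and 34743, 2685 and 10669, and 415 to 6583 counts. A further 5 genes (ADH1, ADH4, ZPS1, ZRT1 and VEL1) were put together as related to zinc. Without Calcofluor 2 of them were higher and 1 lower in mub1 (median 1.669). With Calcofluor 0 differed past the threshold, though the median was 2.024. The planned list of 13 targets of Zap1, the zinc regulator, was not called without Calcofluor (5 higher, 3 lower, adjusted p 0.421) or with it (2 higher, 2 lower, 0.803).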
